A study of Mus musculus with 2 samples.

How the data were processed

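Total RNA from E11.5 mouse limb was sequenced as 2 libraries of 1 group, biological replicates 1 and 2 per the labels, from pools of 109 and 88 embryos. Per the labels, RNA was extracted with the mirVana kit, RNA longer than 200 nt was kept, 10 ng entered each library and spike-in RNAs were used. A Smart-seq protocol document is linked in the labels and its text was not used here. The authors deposited 1 table of genes and 1 of transcripts for each library. Per the file headers these were quantified from transcriptome alignments to mm10 with GENCODE annotation M4, and their column names are those that RSEM writes. The aligner, tool versions and use of strand are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart.

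The authors deposited expected counts, which are estimated reads per gene or transcript that need not be whole and are not normalised. The deposited TPM values are scaled to a fixed total over all entries, spike-ins included, with an effective length 99 nt below the length. The deposited transcript tables also give the percent of a gene's TPM held by each transcript, and the deposited credibility bounds of TPM have a level that is not given in the sources used here. For some genes these bounds do not contain the deposited TPM value. RSEM posterior mean TPM, also deposited, served as an alternative. Each gene table had 69691 entries, of which 43346 were genes, 97 spike-ins and 26248 entries with only a number for a name. Of the number-only entries 11 were above 0, with 6.29e-05% and 4.76e-05% of counts in replicates 1 and 2, and all number-only and spike-in entries were left out of library sizes and tests.

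Symbols, gene types and coordinates came from GENCODE M21 on GRCm38, the same build as mm10. The annotation differs from M4, so gene bounds may differ, and 42462 gene IDs were matched while 884 were not. Expected counts were rounded to whole numbers for edgeR and for the exact test. Libraries were scaled by TMM over genes, which gave effective sizes of 40.4 M and 32.5 M. The biological coefficient of variation came from edgeR with an intercept alone, over genes with at least 10 counts in both libraries. Genes with at least 20 counts over both libraries were compared by an exact two-sided binomial test on the gene's total with Benjamini-Hochberg adjustment at 0.05 and a log2 ratio of at least 1 in size. As the labels give 1 group, no quasi-likelihood contrast could be fitted. Log2 ratios used TMM-scaled CPM with a prior count of 0.5.

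A gene was called detected at 1 TPM in both libraries. Correlations used a pseudocount of 1. Shares of counts carry Wilson intervals at 95%, and a count of 0 allows up to 3 counts. Pairs used a pseudocount of 0.1 and the 95th percentile of absolute between-pool differences among genes in the abundance bin of the lower gene, with 20 bins. List levels were set against 10000 random lists of protein-coding genes of the same size, and list shifts, over members of at least 1 CPM, against 10000 random lists matched on expression in 20 bins. Transcript shares were described for key genes of at least 5 TPM. A smooth on GC content and length, with values for 99.4% of genes, changed the correlation of the log2 ratio with length from a rho of 0.22 to 0.00 and that with GC content from -0.09 to 0.04.

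The 30 gene lists, the 41 pairs, the tests of the main comparisons and the rules for named genes were chosen before the data were examined. The lists were limb mesenchyme, apical ridge and limb ectoderm, the hedgehog, BMP, FGF, WNT and retinoic acid pathways, chondrogenic, hypertrophic cartilage and osteoblast, myogenic progenitor, contractile muscle, tendon and connective tissue, erythroid, endothelial, macrophage, neural crest and Schwann, neuron, spinal cord progenitor, liver, yolk sac and gut, heart, somite and trunk, proliferation, growth arrest and apoptosis, immediate early and heat shock, hypoxia and glycolysis, imprinted, long non-coding RNA, short structured RNA, Y-linked, and X inactivation. Of their 462 entries 3 had no match in the tables, and a gene may stand in more than 1 list. Named were the 4 highest members of each list, a fixed set of key genes, the genes of the pairs, Hox genes of groups 9 to 13 and the 10 highest nuclear protein-coding genes. Between pools, named were up to 10 protein-coding genes in each direction past the test with a mean CPM of at least 10, and every list member past the test. The values of some of these genes are not reported here, while counts and medians include them. Other genes are said to have been chosen after their values were seen.

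The steps were tested on simulated data. With 16771 genes and counting noise alone, the between-pool test recovered 93% of genes changed 4-fold and 95% of those changed 8-fold, with 0 calls among unchanged genes. With no gene changed and a biological coefficient of variation of 0.05 or 0.1, the estimates were 0.0496 over 16767 genes and 0.0997 over 16776 genes, with 30 and 69 calls. Of 400 unshifted lists of 20 genes 5.75% lay outside percentiles 2.5 to 97.5. Alternatives covered scaling by DESeq2 size factors or library size, filters, pseudocounts, posterior means, counts without length correction, assumed variation, and each replicate left out. Added after the data were seen were TPM without spike-ins, the smooth on GC content and length, and protein-coding genes alone. R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.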

Results

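Total RNA was sequenced from the limb of mouse embryos at embryonic day 11.5, a stage at which the limb is a bud of mesenchyme under an ectoderm whose distal edge, the apical ridge, secretes growth factors. The labels give 1 group with 2 biological replicates and name no treatment or contrast. Replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos, each of both sexes and of the strain that the labels call B6NCrl. Each library started from 10 ng of RNA longer than 200 nt, and spike-in RNAs were used. Expected counts over all entries came to 43.0 M in replicate 1 and 35.1 M in replicate 2, of which 40.6 M and 32.3 M fell on genes. For a transcript of 2 kb, 1 count was worth 0.0187 TPM in replicate 1 and 0.0225 TPM in replicate 2. In all, 22361 genes had a count above 0 in replicate 1 and 21917 in replicate 2. Values below are mean TPM ± SD over both libraries (n = 2) unless another unit is named, and a log2 ratio between the pools is always replicate 2 over replicate 1.

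The bud expressed 13563 genes at 1 TPM or more in both libraries, of which 12081 were protein-coding, 495 were pseudogenes, 895 were of other types and 92 had no symbol in the annotation used. At 10 TPM or more in both libraries there were 8295 genes, and at 100 TPM or more 1499. Among nuclear protein-coding genes the highest levels belonged to embryonic globin Hbb-y (5620.3 ± 527), cytoplasmic actin Actb (5513 ± 544), the histone gene Hist1h2ap (5206 ± 361), the prolyl isomerase Ppia (4553 ± 256) and the elongation factor Eef1a1 (4072 ± 314). The ferritin light chain Ftl1 (3746 ± 365), prothymosin Ptma (3358 ± 218), adult-type globin Hba-a2 (3179 ± 369), the ribosomal protein gene Rpl41 (3094 ± 161) and the chaperone Hspa8 (2885 ± 101) completed the top 10. Hba-a2 shares reads with Hba-a1, and Hist1h2ap with other histone genes, so the split between such copies is uncertain.

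Protein-coding genes took 89.8% of the counts in replicate 1 (95% Wilson interval 89.8 to 89.8) and 87.4% in replicate 2 (87.4 to 87.4), a mean of 88.6% ± 1.70 (SD, n = 2). Ribosomal protein genes held 2.63% and 2.47%, histone genes 0.899% and 0.837%, the 8 globin genes 0.530% and 0.472%, and the mitochondrial genome 1.16% and 1.13%. Long non-coding RNAs held 0.927% and 0.953% without Gm42418 and Gm26917, named after their values were seen, which held 1.88% and 1.75% together. The 39 Hox genes, which pattern the body and limb axes, held 0.0922% and 0.0879%. Spike-ins held 5.37% of counts in replicate 1 and 7.92% in replicate 2. On a TPM basis the protein-coding share was 76.6% and the spike-ins held 11.8% and 17.2%, while the mean shares were 6.38% for ribosomal protein genes, 1.58% for histone genes, 1.42% for globins and 2.30% for the mitochondrial genome. Intervals and floors given here cover counting error only, since reads without molecular identifiers are not independent molecules.

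The pools gave nearly the same profile for most genes. Across the 14618 genes with 1 TPM or more in either library, log2(TPM + 1) had a Pearson r of 0.988 and a Spearman rho of 0.989 between replicates; genes are not independent replicates, so no p is attached. The biological coefficient of variation from edgeR over 16118 genes was 7.65%. The SD of the log2 ratio was smaller at higher levels, from 0.56 over 5611 genes at 1 to 10 TPM to 0.24 over 6917 genes at 10 to 100 TPM and 0.09 over 1460 genes at 100 to 1000 TPM. A chi-square of 8.14 per degree of freedom over 16787 genes showed that the libraries differed by more than sampling noise, which does not tell pools from libraries. They were counted as 2 samples because the labels give separate pools.

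**Figure D1:**
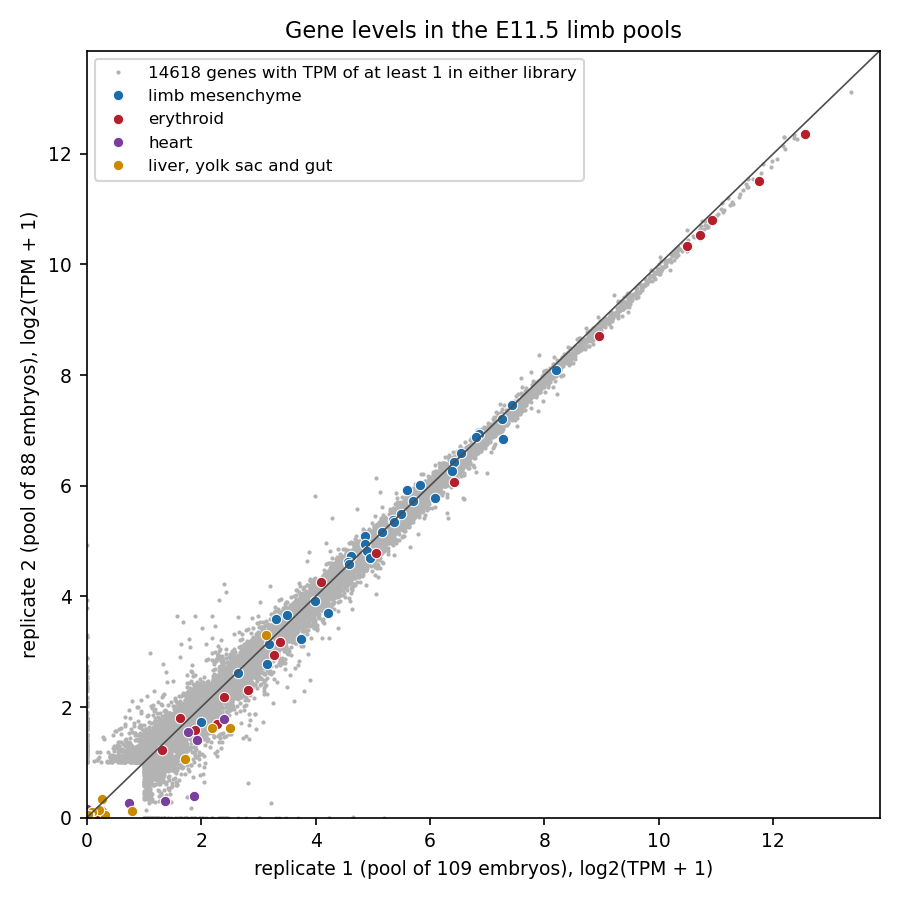
Gene levels in replicate 2 (y axis) against replicate 1 (x axis), both as log2(TPM + 1), for the 14618 genes with 1 TPM or more in either library (grey points), with the members of 4 gene lists in colour and the line of equality. Most limb mesenchyme genes lie near the line, while most heart and liver genes lie near the origin and below it.

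Genes of the limb mesenchyme were expressed throughout: all 33 listed genes reached 1 TPM in both libraries, with a median of 34.8 TPM, above the median of every one of 10000 random lists of protein-coding genes (percentile 100). The ankyrin-repeat gene Asb4 (282 ± 16.2), the homeobox genes Msx1 (174 ± 1.41) and Prrx1 (149 ± 3.49) and the hindlimb homeobox gene Pitx1 (135 ± 28.7) led the list. Tbx5, the T-box gene of the forelimb bud, and Tbx4, that of the hindlimb bud, stood at 24.6 ± 1.60 and 28.1 ± 1.07. The homeobox genes Meis1 and Meis2, which mark the proximal bud, stood at 59.6 ± 5.51 and 40.3 ± 0.509. Fgf10, the mesenchymal signal to the ridge, was at 11.0 ± 1.00, the posterior regulator Hand2 at 23.1 ± 0.643 and the dorsal regulator Lmx1b at 7.96 ± 0.134. Reads of Hand2 cannot be told from those of its antisense neighbour Hand2os1 without strand.

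In GRCm38 coordinates, Tbx5 (ENSMUSG00000018263) lies on chromosome 5, 119832668 to 119885219, Tbx4 (ENSMUSG00000000094) on chromosome 11, 85886422 to 85916097, Pitx1 (ENSMUSG00000021506) on chromosome 13, 55825051 to 55836192, Prrx1 (ENSMUSG00000026586) on chromosome 1, 163245119 to 163313710 and Msx1 (ENSMUSG00000048450) on chromosome 5, 37820485 to 37824583. These are whole annotated genes, exons and introns together. Shh (ENSMUSG00000002633) lies on chromosome 5, 28456815 to 28467256, Fgf8 (ENSMUSG00000025219) on chromosome 19, 45736798 to 45742915 and Sox9 (ENSMUSG00000000567) on chromosome 11, 112782224 to 112787760. Hoxa13 (ENSMUSG00000038203) lies on chromosome 6, 52257694 to 52260880 and Hoxd13 (ENSMUSG00000001819) on chromosome 2, 74668310 to 74671599.

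Ectoderm and ridge genes were present at lower levels. Of 27 genes, 23 reached 1 TPM in both libraries, with a median of 7.96 TPM (percentile 85.0). Keratin Krt14 (37.6 ± 2.91), the ridge signal Fgf8 (34.2 ± 3.40), Perp (33.1 ± 0.311) and the epithelial adhesion gene Epcam (30.5 ± 1.30) were highest. The dorsal ectoderm signal Wnt7a stood at 2.00 ± 0.0212, the ventral regulator En1 at 1.5 ± 0.304, and the ridge signal Fgf4 at 0.355 ± 0.318, from 11 and 40 counts in replicates 1 and 2.

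Components of the signalling pathways that pattern the bud were broadly present, while the ligand Shh stood close to 1 TPM. In the hedgehog list 13 of 15 genes reached 1 TPM in both libraries (median 13.4 TPM, percentile 90.2). Its co-receptor Gas1 was at 149 ± 14.2, the transducer Smo at 54.3 ± 3.23, Sufu at 34.6 ± 0.721, the transcription factor Gli3 at 31.9 ± 1.00 and the receptor Ptch1 at 16.4 ± 0.382, while Shh, the ligand of the posterior organising region, was at 1.02 ± 0.0283. The BMP list had 19 of 19 genes detected (median 21.0 TPM, percentile 98.2), with the target genes Id3 (429 ± 45.1), Id2 (287 ± 24.5) and Id1 (180.2 ± 22.7) highest, followed by the receptor Bmpr1a (54.0 ± 1.37). The ligand Bmp4 was at 41.7 ± 3.01 and the antagonist Grem1 at 5.88 ± 0.346. The FGF list had 14 of 15 detected (median 14.7 TPM, percentile 92.5), led by the phosphatase Dusp6 (147 ± 5.63), the receptor Fgfr1 (94.0 ± 0.325), the feedback inhibitor Spry2 (55.4 ± 1.45) and Fgfr2 (53.9 ± 2.82). The WNT list was detected in full, 23 of 23 genes (median 15.4 TPM, percentile 96.6), with beta-catenin Ctnnb1 at 511 ± 12.5, Tcf7l2 at 171 ± 3.32, the secreted antagonist Sfrp2 at 123 ± 8.36 and the ligand Wnt5a at 86.2 ± 1.24. Of the retinoic acid list 13 of 16 genes were detected (median 13.6 TPM, percentile 91.1), with the binding proteins Crabp2 (626 ± 50.8) and Crabp1 (251 ± 46.3), the receptor Rarg (90.5 ± 3.44) and the reductase Dhrs3 (37.6 ± 2.64) on top.

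Most cartilage genes were detected and most hypertrophic and bone genes were not. Of the chondrogenic list 17 of 20 genes reached 1 TPM in both libraries (median 12.4 TPM, percentile 92.3), led by the collagen Col2a1 (185 ± 5.76), the cartilage regulator Sox9 (162 ± 11.1), Wwp2 (69.1 ± 5.66) and Col9a1 (61.4 ± 3.58). Of the hypertrophic cartilage and osteoblast list only 5 of 13 did (median 0.325 TPM, percentile 14.5). The parathyroid hormone receptor Pth1r (25.5 ± 2.52), osteopontin Spp1 (5.78 ± 2.91), the osteoblast regulator Runx2 (4.42 ± 0.191) and Alpl (2.94 ± 0.877) were the highest of these. Collagen Col10a1, a hypertrophic marker, had 13 and 7 counts (0.125 ± 0.0354). Tendon and connective tissue genes were high, with 13 of 14 detected and a median of 37.3 TPM (percentile 99.8), from the collagens Col3a1 (352 ± 15.5) and Col1a2 (197 ± 3.20) to fibronectin Fn1 (127 ± 7.67). The list also holds the E-protein gene Tcf4 (166 ± 3.52), which is not the connective tissue marker of that alias, Tcf7l2.

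Muscle lineage genes were present from progenitor to early contractile stages. Of the myogenic progenitor list 12 of 14 genes were detected (median 9.39 TPM, percentile 80.7), with the differentiation factor Myog (23.7 ± 0.552), Six4 (19.2 ± 1.17) and the determination factor Myod1 (17.2 ± 0.212) among the highest. Myf5, another determination factor, stood at 15.1 ± 1.30 and Pax3, which marks migrating progenitors, at 4.06 ± 0.495. Of the contractile list 16 of 19 were detected (median 5.08 TPM, percentile 65.7), led by cardiac-type actin Actc1 (69.2 ± 8.89), troponin Tnnt1 (47.6 ± 5.07), myosin light chain Myl1 (20.8 ± 1.22) and Tnnc1 (13.6 ± 1.75).

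Blood and vessel genes were present as well. The erythroid list had 17 of 18 genes detected (median 13 TPM, percentile 92.2), where embryonic zeta-globin Hba-x was at 1872 ± 121 and Hba-a1 at 1584 ± 145, beside Hbb-y and Hba-a2. The endothelial list had 17 of 19 detected (median 13.5 TPM, percentile 93.0), with Egfl7 (54.0 ± 4.77), Plvap (44.0 ± 2.18), Esam (22.2 ± 2.62) and Pecam1 (19.5 ± 1.58) on top and the VEGF receptor Kdr at 15.4 ± 1.38. Macrophage genes were lower, 13 of 15 detected with a median of 3.10 TPM (percentile 51.0), such as the complement gene C1qb (12.6 ± 0.488), Fcer1g (10.3 ± 0.233), lysozyme Lyz2 (8.65 ± 0.566), Tyrobp (8.05 ± 2.55) and the receptor Csf1r (4.51 ± 0.785).

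Nerve-associated genes were low and spinal cord genes were near background. In the neural crest and Schwann list 7 of 13 genes were detected (median 2.04 TPM, percentile 42.3), with Tfap2b (26.2 ± 2.29), Ngfr (9.89 ± 1.03), Erbb3 (6.0 ± 0.00707) and Tfap2a (4.96 ± 0.0424) highest and the crest regulator Sox10 at 2.77 ± 0.474. In the neuron list 7 of 12 were (median 2.21 TPM, percentile 39.3), led by Isl1 (13.6 ± 1.68), Dcx (8.40 ± 1.15), Tubb3 (7.89 ± 1.39) and Stmn2 (4.73 ± 0.622). None of the 8 spinal cord progenitor genes reached 1 TPM in both libraries, and together they held 14 counts in replicate 1 and 21 in replicate 2 (median 0.0400 TPM, percentile 4.39). The highest of them were Pax6 (0.125 ± 0.0495) and Nkx6-1 (0.0550 ± 0.0495). Pax6 had 5 and 7 counts in replicates 1 and 2. Its deposited TPM bounds (0.585 to 1.43 and 0.774 to 1.85) lay above its TPM in each library and reached past 1 TPM.

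Lists named for tissues outside the limb had low medians, though some of their genes were measurable. Membership in such a list does not show that a gene is absent from limb cells, so these levels need not come from other tissue. Of the liver, yolk sac and gut list 4 of 12 reached 1 TPM in both libraries (median 0.188 TPM, percentile 7.75): transferrin Trf (8.30 ± 0.799), alpha-fetoprotein Afp (3.40 ± 1.85) and the apolipoproteins Apoa2 (2.82 ± 1.06) and Apoa1 (1.69 ± 0.834). Of the heart list 3 of 8 did (median 1.21 TPM, percentile 29.3), with troponin Tnni3 (3.37 ± 1.32), the atrial light chain Myl7 (2.23 ± 0.827) and Hand1 (2.17 ± 0.325). Of the somite and trunk list 6 of 10 did (median 2.32 TPM, percentile 40.4), led by Tcf15 (17.5 ± 3.51), Meox1 (8.90 ± 0.615), Hoxc6 (7.82 ± 1.12) and Pax1 (5.87 ± 0.453).

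Cell cycle genes were among the highest groups: all 20 proliferation genes were detected, with a median of 211 TPM (percentile 100) and the mitotic kinase Cdk1 (406 ± 23.6), Rrm2 (353 ± 8.99), Top2a (333 ± 0.870) and Pcna (313 ± 14.8) on top. Of the growth arrest and apoptosis list 12 of 14 were detected (median 28.5 TPM, percentile 99.2), among them the imprinted cell cycle inhibitor Cdkn1c (623 ± 42.0), Trp53 (193 ± 6.17) and Bax (133 ± 1.63). The hypoxia and glycolysis list had 14 of 15 genes detected (median 85.2 TPM, percentile 100), with the glycolytic enzymes Eno1 (1742 ± 141), Ldha (1547 ± 194), Tpi1 (595 ± 82.7) and Aldoa (577 ± 54.8) highest. Of the immediate early and heat shock list 10 of 15 were detected (median 2.25 TPM, percentile 44.9), led by Ier2 (117 ± 1.38), Hsph1 (90.4 ± 9.33), Dnajb1 (78.3 ± 5.57) and Jun (27.8 ± 8.52).

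All 20 imprinted genes were detected, with a median of 70.9 TPM (percentile 100), led by Mest (2289 ± 193), Gnas (1097 ± 17.3), the growth factor Igf2 (654 ± 13.4) and Cdkn1c. Of the long non-coding RNA list 12 of 14 were detected (median 14.2 TPM, percentile 91.2), with the nuclear RNA Malat1 at 2206 ± 8.03, H19 at 511 ± 15.4, Gas5 at 493 ± 16.3 and Hoxa11os, which overlaps Hoxa11 on the other strand, at 281 ± 2.67. Of the short structured RNAs 5 of 10 were detected (median 13.7 TPM, percentile 86.5), with the signal recognition particle RNA copies Rn7s2 (4857 ± 282) and Rn7s1 (4856 ± 282), which share reads, far above Rn7sk (202 ± 1.56) and Rpph1 (59.2 ± 5.35). Each pool held both sexes per the labels. All 4 Y-linked genes were detected (median 15.5 TPM, percentile 75.1), from Eif2s3y (22.8 ± 0.346) and Ddx3y (18.1 ± 2.31) to Kdm5d (12.9 ± 2.36) and Uty (11.3 ± 1.51), and so were all 4 genes of the X inactivation list (median 5.41 TPM, percentile 48.6), with Xist at 19.3 ± 2.26, Ftx at 6.81 ± 0.438, Jpx at 4.01 ± 0.163 and Tsix, which overlaps Xist, at 2.08 ± 0.354. In all, 7 of the 30 lists had a median in the top 2.5% of random lists, a count that lists of known markers are bound to lift.

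**Figure D2:**
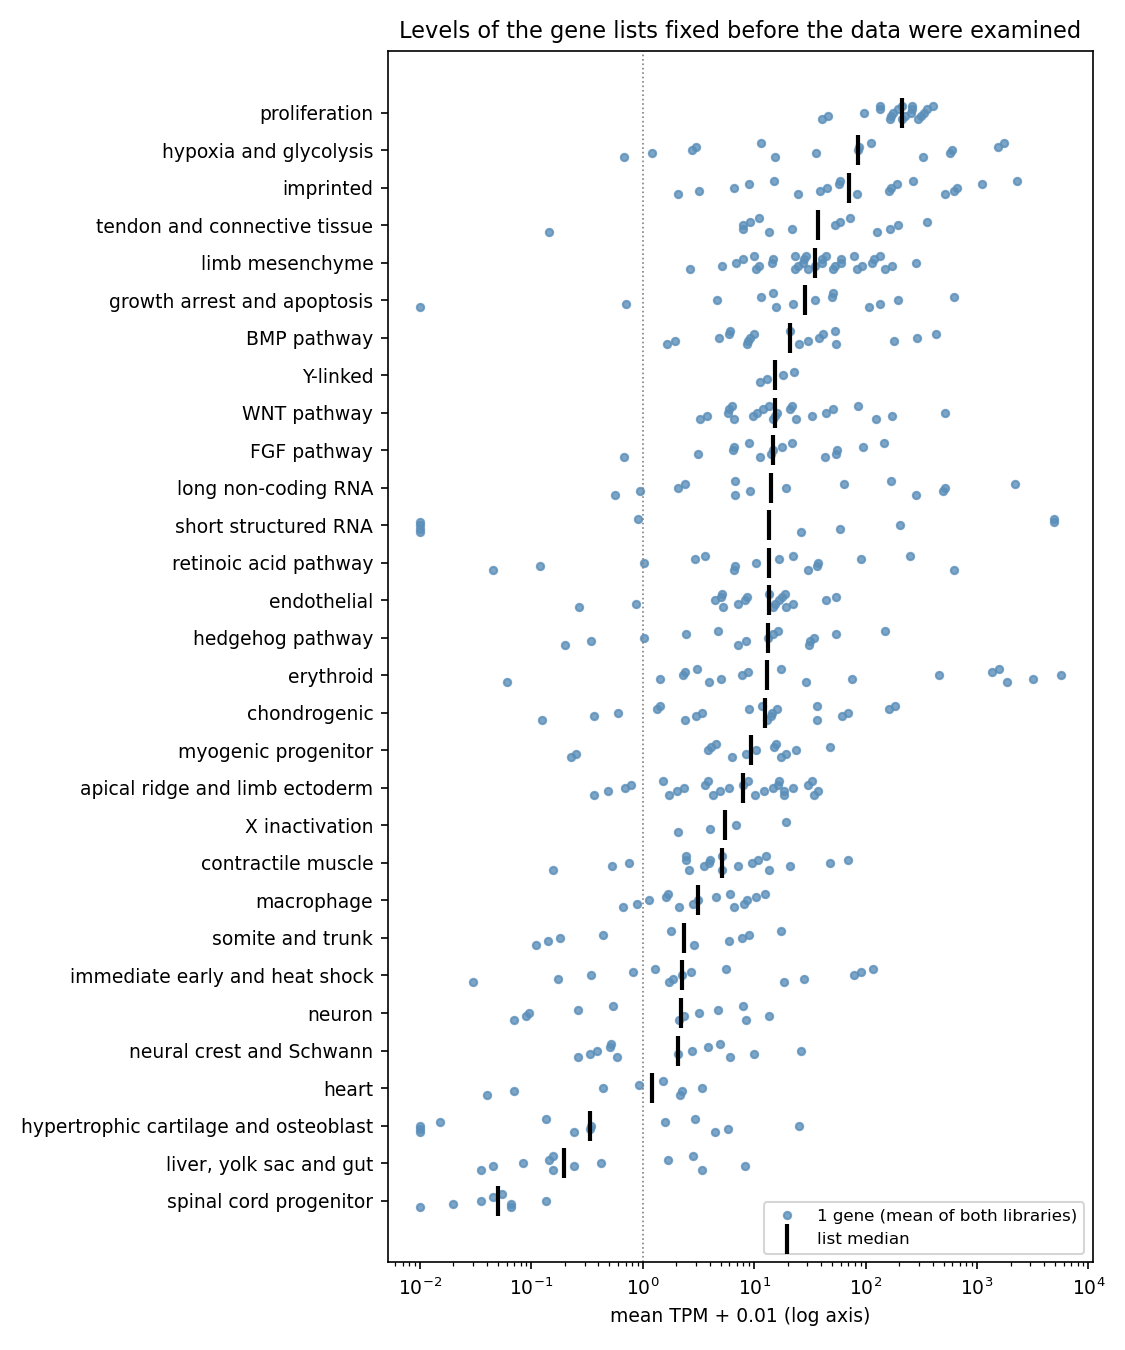
Mean TPM + 0.01 over both libraries (log axis) of each gene in the 30 lists, 1 point per gene, with the list median as a black bar and a dotted line at 1 TPM. Proliferation genes have the highest median at 211 TPM and spinal cord progenitor genes the lowest at 0.0400 TPM.

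Expression of the Hox clusters was concentrated in the 5′ genes of HoxA and HoxD, the genes that pattern the limb along its proximal to distal axis. Hoxa10 (212 ± 11.9), Hoxa9 (69.1 ± 5.44) and Hoxa11 (55.7 ± 3.75) were the highest genes of HoxA, where Hoxa13, a gene of the distal bud, stood at 21.1 ± 1.67. In HoxD the order was Hoxd12 (62.5 ± 2.04), Hoxd11 (47.5 ± 0.453), Hoxd13 (44.2 ± 4.46), Hoxd10 (41.0 ± 0.276) and Hoxd9 (15.9 ± 4.52). HoxC was led by Hoxc10 (38.5 ± 8.44), with Hoxc9 (4.07 ± 1.1), Hoxc11 (4.37 ± 0.389), Hoxc13 (1.79 ± 0.134) and Hoxc12 (0.815 ± 0.0778) far lower. Hoxb9 was at 1.34 ± 0.156 and Hoxb13 had 0 counts in replicate 1, which allows up to 0.0506 TPM, and 3 in replicate 2.

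Summed over genes, HoxA held 390.3 ± 12 TPM, HoxD 223 ± 12.6, HoxC 71.9 ± 10.8 and HoxB 16.6 ± 2.06. Of 39 Hox genes 29 reached 1 TPM in both libraries, 9 of 11 in HoxA, 5 of 10 in HoxB, 8 of 9 in HoxC and 7 of 9 in HoxD. Paralogue groups 9 to 13 of HoxA and HoxD together made up 81.1% ± 0.612 of all Hox TPM (SD, n = 2), 51.0% from HoxA and 30.1% from HoxD. Groups 1 to 8 summed to 32.5 TPM in HoxA, 15.2 in HoxB, 22.4 in HoxC and 11.8 in HoxD. Hoxa11 and Hoxa13 overlap or adjoin the non-coding genes Hoxa11os and Hottip, from which their reads cannot be told apart without strand.

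**Figure D3:**
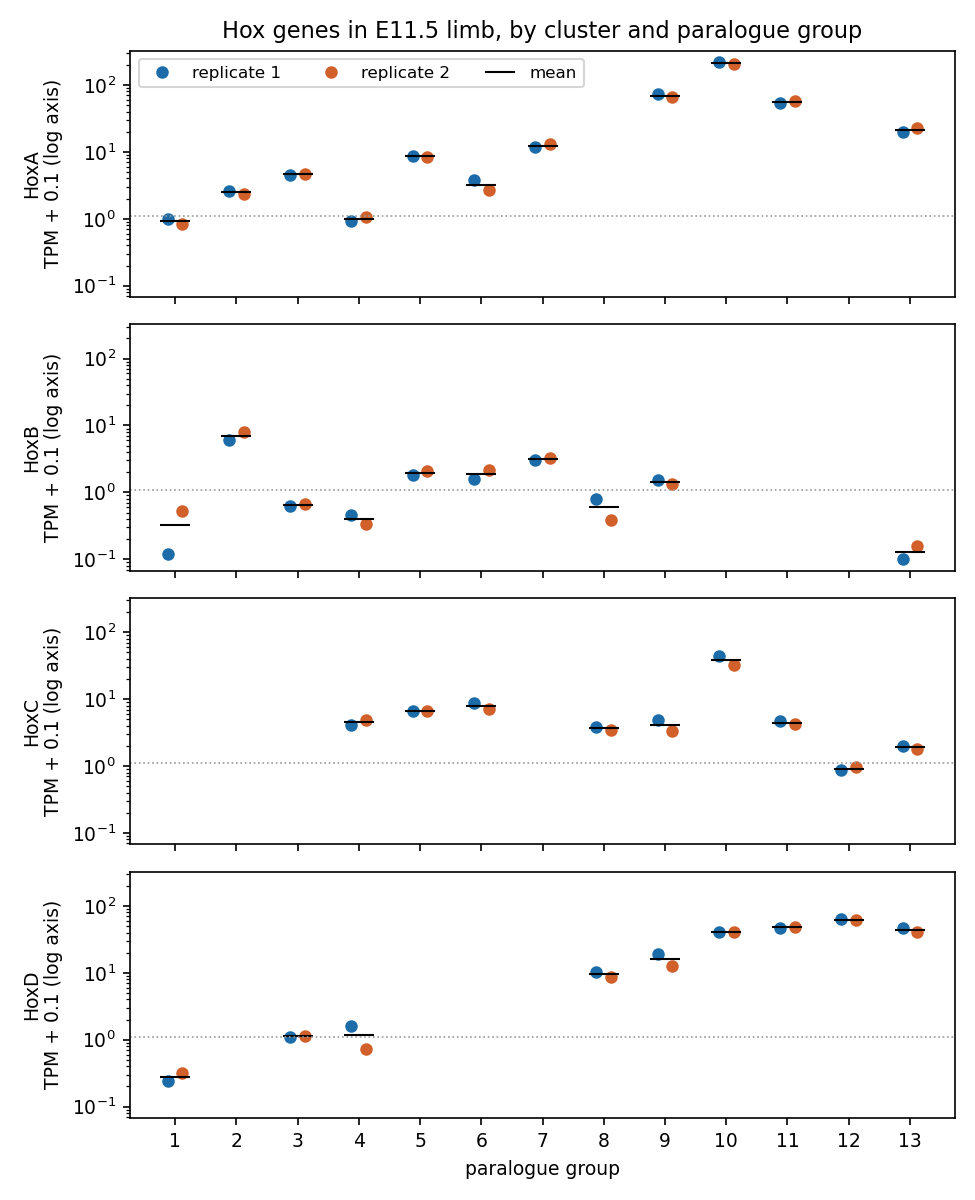
TPM + 0.1 (log axis) of each Hox gene in replicate 1 (blue) and replicate 2 (orange) by paralogue group, 1 panel per cluster, with the mean as a black bar and a dotted line at 1 TPM. The highest mean is that of Hoxa10 at 212 TPM, and HoxB has no gene above 10 TPM.

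Fixed pairs of genes were then compared within each library, to ask which of 2 related genes was the more abundant. Pitx1 exceeded Tbx4 by a log2 ratio of 2.24 ± 0.25 (SD, n = 2) and Tbx5 lay below Pitx1 (-2.43 ± 0.40), while Tbx5 and Tbx4 differed by less than the spread between pools (-0.19 ± 0.15, limit 0.33). Hoxd13 exceeded Hoxa13 (1.06 ± 0.26) and Hoxc13 (4.54 ± 0.04), Hoxa11 exceeded Hoxa13 (1.40 ± 0.02), and Hoxa10 exceeded Hoxa11 (1.93 ± 0.18). Hoxd11 and Hoxd13 differed by less than the spread (0.11 ± 0.16, limit 0.29). In all, 37 of the 41 pairs had the same sign in both libraries and a mean log2 ratio beyond the limit. The limit is the 95th percentile of between-pool differences at the abundance of the lower gene. It measures how far 1 gene varies between the pools, not the error of setting different genes side by side. The share of random pairs beyond it was not computed, so the count of 37 is a description only. An exact two-sided sign test over 2 libraries cannot go below p = 0.5, and no p is given.

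Among signals and receptors, Fgf8 exceeded Fgf4 (6.43 ± 1.25), Gli3 exceeded Gli1 (2.14 ± 0.19) and Gli2 (1.25 ± 0.00), Grem1 exceeded Nog (1.55 ± 0.23), Bmp4 exceeded Bmp2 (2.04 ± 0.12), and Wnt5a exceeded Wnt7a (5.36 ± 0.01). Fgfr1 was above Fgfr2 (0.80 ± 0.08) and Fgfr3 (3.39 ± 0.06), Rarg above Rarb (3.11 ± 0.10), and Etv4 below Etv5 (-1.0 ± 0.21). Shh and Ihh did not separate beyond the limit of 2.72 (1.44 ± 0.55), with 14 and 25 counts on Ihh. Fgf10 was below Fgf8 (-1.63 ± 0.27), Bmp7 below Bmp4 (-0.46 ± 0.10) and the retinoic acid-degrading enzyme Cyp26b1 below the synthetic enzyme Aldh1a2 (-0.46 ± 0.01). The sign of these last 3 ratios turned without length correction, to 0.48, 0.44 and 0.63 on expected counts.

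Among regulators of the bud, Msx1 exceeded Msx2 (2.58 ± 0.05), Prrx1 exceeded Prrx2 (0.40 ± 0.09) and Hand2 exceeded Hand1 (3.36 ± 0.25). The mesenchymal gene Lmx1b exceeded the ectodermal gene En1 (2.35 ± 0.30), and Meis2 was below Meis1 (-0.56 ± 0.15). Col2a1 exceeded Col10a1 by 9.69 ± 0.18 and Col1a1 lay below Col2a1 (-1.34 ± 0.12), while Sox9 exceeded Runx2 (5.16 ± 0.04). In the muscle lineage Pax3 exceeded Pax7 (3.72 ± 0.27), Myod1 lay below Myog (-0.46 ± 0.02), and Myf5 and Myod1 did not separate (-0.19 ± 0.11, limit 0.43). The embryonic globins Hbb-y (3.62 ± 0.04) and Hbb-bh1 (1.59 ± 0.06) exceeded adult-type Hbb-bt, and Hba-x exceeded Hba-a1 by 0.24 ± 0.04. The last ratio passed the limit of 0.23 on the mean but not in replicate 1 alone (0.22). Hba-a1 shares reads with adult-type Hba-a2, which at 3179 ± 369 TPM stood above Hba-x at 1872 ± 121 TPM. This ratio therefore does not rank embryonic above adult-type alpha-globin. Igf2 was above H19 (0.36 ± 0.01), Ccnd1 below Ccnd2 (-0.77 ± 0.24), Lin28b above Lin28a (3.42 ± 0.32) and Tsix below Xist (-3.16 ± 0.07). Without length correction, with the limit set on counts corrected for depth, Myod1 against Myog (-0.13, limit 0.35) lost its call and Shh against Ihh (1.85, limit 1.71) gained one.

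**Figure D4:**
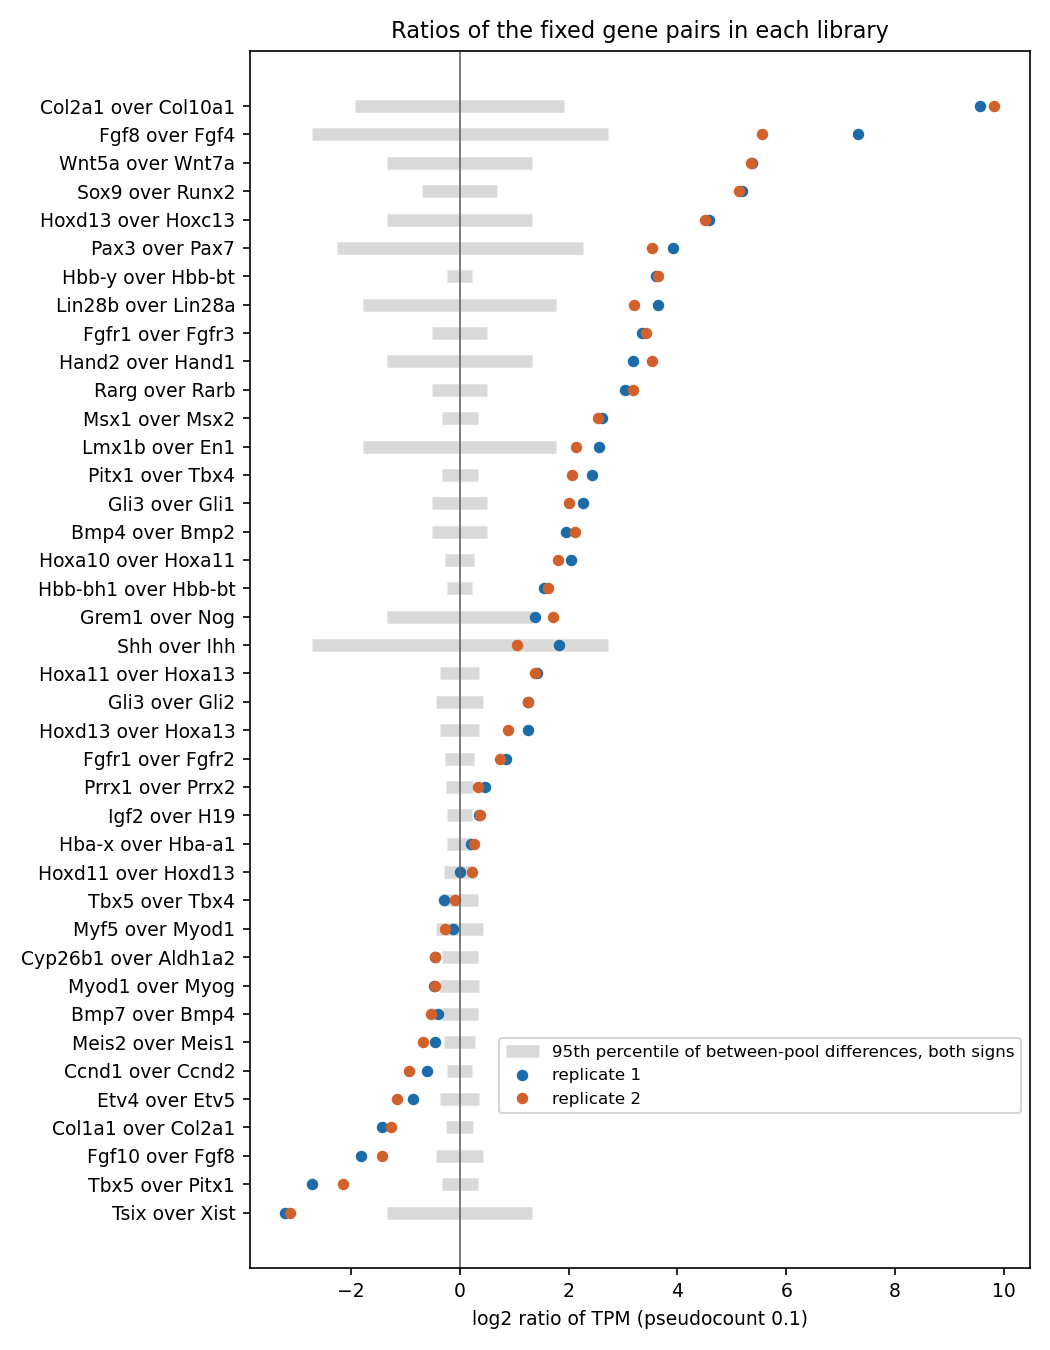
Log2 ratio of TPM (pseudocount 0.1) of the fixed gene pairs, except 1 that is not reported, in replicate 1 (blue) and replicate 2 (orange), with a grey bar for the 95th percentile of between-pool differences in both signs. The mean ratio lies outside the bar in all pairs drawn but 4, which are Tbx5 over Tbx4, Hoxd11 over Hoxd13, Shh over Ihh and Myf5 over Myod1.

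Transcript shares were then described for the 29 key genes of 5 TPM or more, to ask how much of each gene came from its leading transcript. Sox9, Hoxd12, Hoxd13, Hand2, Myod1, Myog, Tbx5 and others, 10 genes in all, had only 1 transcript in the deposited tables. Among the other 19 the leading transcript held a median of 78.0% of the gene's TPM, with 99.7% ± 0.115 for Kdr and 98.6% ± 1.5 for Hoxa13 among the highest and 37.1% ± 2.33 for Prrx1, 32.7% ± 5.25 for Fgf8 and 26.7% ± 14.5 for Meis2 the lowest (SD, n = 2). It held over 90% in 7 genes and under 60% in 5. Over all 29 genes the median was 97.1%.

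Among the 19 genes with more than 1 transcript, most shares differed little between pools, by a median of 2.13 percentage points. The widest gap was 20.6 points in Meis2, whose leading transcript stood at 15.0 TPM in replicate 1 and 6.54 TPM in replicate 2. The deposited credibility bounds of those values overlapped, at 7.47 to 15.7 and 4.02 to 14 TPM. In Fgf8 the transcript with the highest mean and the next held 36.4% and 24.8% in replicate 1 against 29.0% and 29.7% in replicate 2, so the higher value lay on a different transcript in each library. In Wnt5a the corresponding transcripts held 42.8% and 44.8% against 46.0% and 43.0%. Such shares are estimates, because reads shared by transcripts are divided by a model.

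Between the pools, several genes of heart, liver and contractile muscle were lower in replicate 2. Of the 33 limb mesenchyme genes 0 passed the test, which few abundant genes did: only 2 of all genes with a mean CPM of at least 10 passed. The ventricular light chain Myl2 fell, with 41 and 2 counts in replicates 1 and 2 (log2 ratio -3.74 [-7.13 to -2.10], 95% counting interval), as did the atrial peptide Nppa with 34.3 and 4.2 counts (-2.57 [-4.73 to -1.28]) and the atrial myosin Myh6 with 112 and 28.2 (-1.65 [-2.34 to -1.08]). Albumin Alb fell with 40 and 4 counts (-2.85 [-4.95 to -1.54]), Afp with 263 and 97 (-1.12 [-1.47 to -0.78]), and the myosins Myh8 and Myh7 had ratios of -2.61 [-4.45 to -1.42] and -1.30 [-1.85 to -0.78]. Counts of Nppa, Myh6, Myh7 and Myh8 are not whole, so some of their reads were shared with other entries and the split is uncertain. The calls of these myosins need not be independent. Fgf4 was the only list member past the test that rose, with 11 and 40 counts (2.13 [1.19 to 3.29]). Among the 11 list members past the test, the deposited TPM bounds of the 2 libraries overlapped in 4, which were Myl2 (3.14 to 6.12 and 0.812 to 3.23), Myh6 (0.769 to 1.81 and 0.326 to 1.39), Myh7 (0.645 to 1.33 and 0.232 to 0.775) and Hotairm1 (6.1 to 11.1 and 3.20 to 7.69). The TPM values of Myl2 (2.68 and 0.32) and of Myh6 (0.66 and 0.2) lay below the bounds of their own libraries. Overlap of the bounds therefore does not measure the uncertainty of these TPM values. The test compares these 2 libraries only and covers counting error alone, and it cannot tell the pools from their libraries.

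Of 16787 genes with at least 20 counts, 518 differed beyond counting noise by at least 1 in log2 ratio (exact two-sided binomial test, Benjamini-Hochberg 0.05), 249 higher and 269 lower in replicate 2. They were mostly low: their median was 44 counts over both libraries and 443 had fewer than 100. Protein-coding genes made up 346 of them, long non-coding RNAs 112 and pseudogenes 50. The only protein-coding gene among them with a mean CPM of at least 10 was Dlg3, a synaptic scaffold gene (ENSMUSG00000000881, chromosome X, 100767722 to 100818410), which fell with 810 and 321 counts, a log2 ratio of -1.02 [-1.21 to -0.83]. With an assumed biological coefficient of variation of 0.1 the edgeR exact test called 164 genes, and with 0.2 it called 49. Without a minimum ratio 4975 genes passed. With the minimum ratio kept and at least 100 counts over both libraries required, 75 passed.

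Of the 412 list members tested 11 passed, 10 lower and 1 higher. Summed over lists this is 11 calls adjusted over all genes and 13 adjusted over the list alone. Beyond the heart, liver and muscle genes, those that fell were osteopontin Spp1 (-1.03 [-1.36 to -0.71]), the heat shock gene Hspa1a (-2.42 [-2.96 to -1.93]), which shares reads with its copy Hspa1b, and the HoxA antisense RNA Hotairm1 (-1.1 [-1.86 to -0.43]). The heart list had 3 calls by either adjustment, the liver, yolk sac and gut list 2, contractile muscle 2, apical ridge and limb ectoderm 1, immediate early and heat shock 1 and long non-coding RNA 1. Hypertrophic cartilage and osteoblast had 1 call over all genes and 2 adjusted over the list alone, and the hedgehog list 0 and 1. All other lists had 0 calls by either adjustment. At an assumed biological coefficient of variation of 0.2 in the edgeR exact test, only Myl2 and Hspa1a of these 11 still passed, and at 0.1 only Hotairm1 was lost. Dlg3 passed at 0.1 and not at 0.2.

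Whole lists also shifted. Of the 29 lists with a value 10 had a median log2 ratio outside the middle 95% of 10000 random lists matched on expression. Chance gives 1.45 if the genes of a list vary independently, as they did in the simulated lists. Genes of 1 list can vary together, which can raise the number that chance gives, so 10 against 1.45 is a description and no test. The liver, yolk sac and gut list (median -0.99, percentile 0.0200) and the heart list (-0.72, percentile 1.23) had the largest shifts, each over only 3 members of at least 1 CPM. The erythroid list stood at -0.19 (percentile 0; 15 of 17 members lower), with Hbb-y at -0.14 and Hba-a2 at -0.19. The contractile list stood at -0.18 (percentile 0.440; 13 of 18 lower), with Actc1 at -0.21, and the Y-linked list at -0.22 (percentile 0.420; 3 of 4 lower).

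The chondrogenic list stood at -0.15 (percentile 0.010; 13 of 18 lower) with Sox9 at -0.09 and Col2a1 at 0.01, and the retinoic acid list at -0.14 (percentile 0.120; 12 of 14 lower) with Crabp1 at -0.33, Aldh1a2 at -0.25 and Cyp26b1 at -0.24. Hypoxia and glycolysis stood at -0.12 (percentile 0.0700; 11 of 13 lower) with Ldha at -0.21 and Tpi1 at -0.24. The lists that shifted up were limb mesenchyme (0.05, percentile 99.2; 21 of 33 higher) and apical ridge and limb ectoderm (0.12, percentile 99.2; 16 of 23 higher). Within the limb mesenchyme list 12 genes went the other way, among them Pitx1 (-0.38 [-0.43 to -0.33]). Irx5 (-0.52), Irx3 (-0.50) and Alx4 (-0.39), chosen after their values were seen, fell at least as far. Tbx5 was at 0.18 and Tbx4 at -0.02. Hoxc10 stood at -0.40 and Hoxd9 at -0.54. After a smooth on GC content and length the limb mesenchyme and hypoxia calls ended, at percentiles 94.9 and 2.64, and among genes of at least 10 CPM the chondrogenic and contractile calls ended, at 3.51 and 3.85.

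The other lists lay inside the random range. Median log2 ratios were -0.01 for proliferation, 0.01 for imprinted genes, 0.00 for tendon and connective tissue, 0.00 for myogenic progenitors, 0.02 for long non-coding RNAs, 0.02 for the hedgehog list, 0.03 for WNT and 0.05 for FGF. They were 0.07 for BMP (percentile 97.2), 0.06 for short structured RNAs, 0.08 for macrophages, 0.14 for neurons, 0.13 for X inactivation, with Xist at 0.31, and 0.19 for hypertrophic cartilage and osteoblasts. They were -0.02 for growth arrest and apoptosis, -0.03 for neural crest and Schwann cells, -0.04 for immediate early and heat shock genes, -0.08 for the endothelium (percentile 5.64) and -0.19 for somite and trunk (percentile 5.92). The spinal cord list had no member of at least 1 CPM and so no shift. The BMP (98.5) and short structured RNA (99) lists passed among genes of at least 10 CPM, and the endothelial (2.13) and neuron (99.7) lists on TPM. Spike-in totals as the scale would have moved the median of all genes by -0.59, against -0.01 with TMM factors; the shifts above are relative to the latter.

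**Figure D5:**
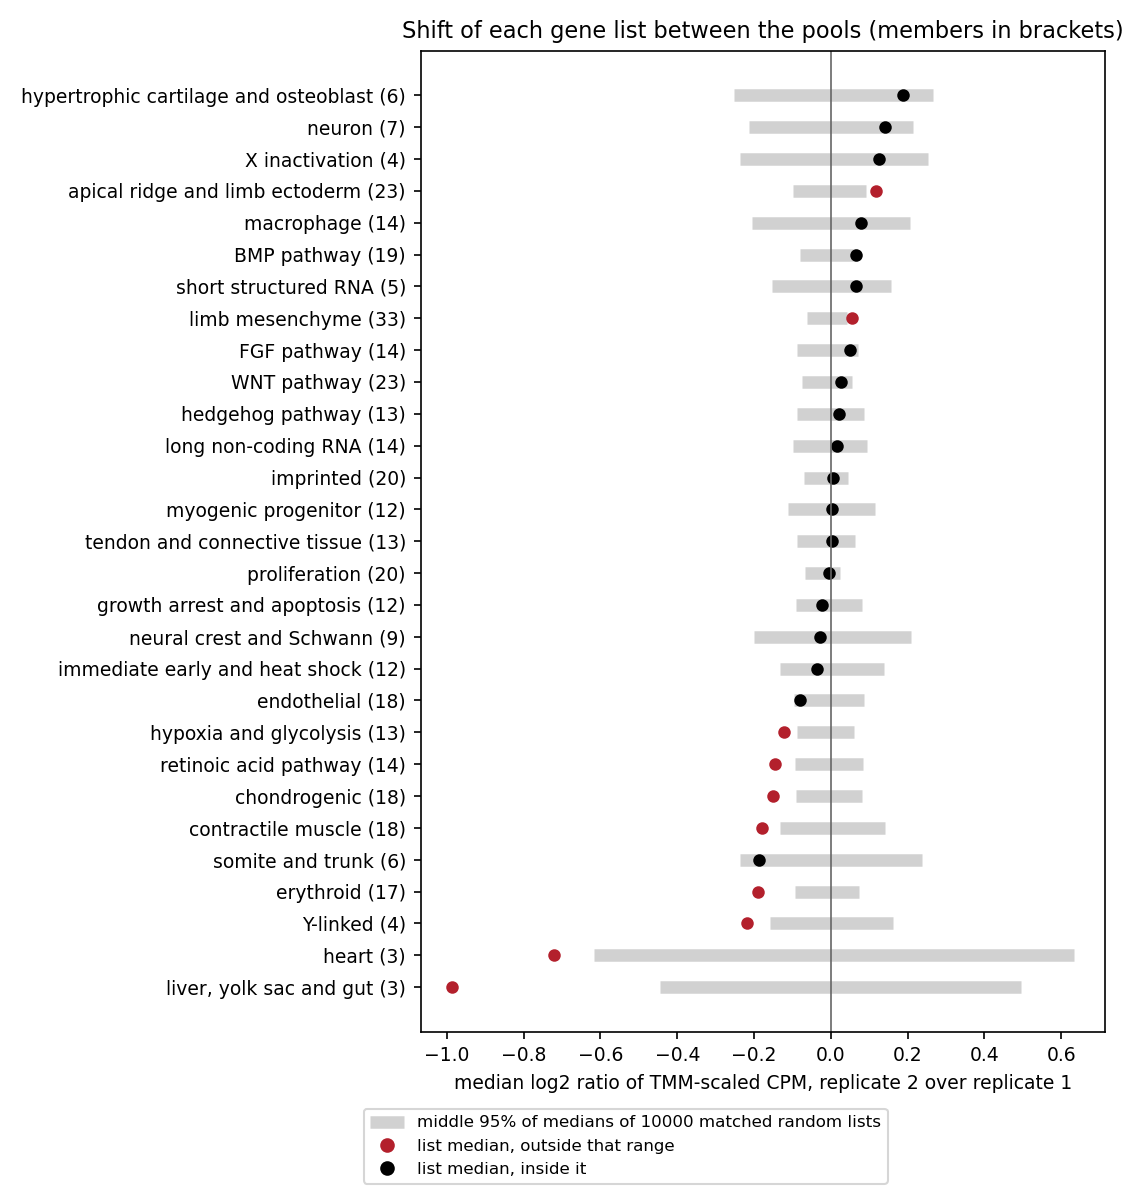
Median log2 ratio of TMM-scaled CPM, replicate 2 over replicate 1, of each gene list (points, red where outside the grey bar) with the middle 95% of medians of 10000 random lists matched on expression (grey bars) and the number of members in brackets. The liver, yolk sac and gut list lies lowest at -0.99, and 10 of 29 lists lie outside their bars.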

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

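The tests of counting noise, of muscle share, of hindlimb share and of GC content and length were chosen only after the result was seen. Spike-ins, which no comparison of genes used, held 5.37% of counts in replicate 1 and 7.92% in replicate 2. Entries named only by a number, which no comparison used either, held 27 counts in replicate 1 and 16.7 in replicate 2, above the 3 counts that a count of 0 allows.

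Many heart and liver genes were lower in replicate 2. The summed lists had 1316 and 636 counts (log2 ratio -0.73), and of their 20 genes 16 were lower, 8 with an interval wholly below 0, 7 reached 1 TPM in both libraries and 0 stood in other lists. Shbg, Cubn, Foxa1 and Nkx2-5 were not lower, with 10 counts or fewer in each library. A candidate explanation is carry-over of heart and liver tissue into the first pool, and the sum of 20 other genes fixed beforehand fell as it predicts (1097 and 649 counts, log2 ratio -0.44, upper bound -0.30). An exact two-sided binomial test of the same sum gave p = 4.89e-10, which adds nothing to an upper bound below 0. Both take reads as independent, so they cover counting error only. Of these genes 17 were lower, 6 with an interval wholly below 0, while Ryr2 was opposite with 9 and 26 counts, Serpina1a had 1.44 and 1.32 (log2 ratio 0.22) and Ahsg had 0 in both. Of these 20, 6 reached 1 TPM in both libraries. At least 5 are also used in skeletal muscle, which are Actn2, Sln, Myom1, Csrp3 and Smpx. Without those 5 and Rbp4 the ratio was -0.65 (-0.96 to -0.36), but this sum kept Pln and Myl3 and need not be free of muscle. A different share of muscle was argued against for the liver genes, as the liver, yolk sac and gut list (-0.64, -0.81 to -0.48) and liver genes outside it (-0.91, -1.30 to -0.55) fell further than the contractile muscle list (-0.20, -0.25 to -0.16), and the median of myogenic progenitors was 0.00. The liver list had been picked for its shift, so here the genes outside it count, with 200 and 85.3 counts. These intervals too cover counting error only. A different share of muscle stays open for the heart genes, as the heart list fell further than muscle (-0.95, -1.23 to -0.70) but the interval of heart genes outside it overlapped with that of muscle (-0.35, -0.51 to -0.20). The contractile list is also no measure of skeletal muscle alone, as it holds cardiac-type actin Actc1 (2922 and 2023 counts). Carry-over stays open for both, though the most abundant liver gene Trf stood at only 8.30 ± 0.799 TPM and, with 432 and 275 counts, was lower in counts but higher in TPM (7.74 and 8.87) in replicate 2, and no biological explanation was tested since the labels give 1 group.

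Pitx1 and Hoxc10 were lower in replicate 2, with log2 ratios of -0.38 and -0.40. In the limb mesenchyme list, where 21 of 33 genes were higher, this fall was not particular to Pitx1. Irx5 (-0.52), Irx3 (-0.50) and Alx4 (-0.39), chosen after their values were seen, fell at least as far as Pitx1. The smooth on GC content and length took off little, as the mean of Pitx1 and Hoxc10 was -0.39 before and -0.37 after it. The upper counting bounds after the smooth were -0.28 and -0.32. Both bounds still lay on the side of a fall, which would count against such a trend as the whole cause. But both genes were picked for their fall, which favours that outcome, so no conclusion is drawn from the bounds. A smaller hindlimb share in the second pool stays open. Tbx4 lay 0.36 above Pitx1, past the upper limit of random differences (-0.31 to 0.34). A gap past that limit would count against this explanation. That reading was set aside because Pitx1 was picked for its fall, which widens the gap. While Tbx4 itself held at -0.02 [-0.10 to 0.07], the forelimb gene Tbx5 rose (0.18 [0.10 to 0.26]) and Hoxc9 fell (-0.51 [-0.79 to -0.24]). Isl1, used in the hindlimb field and in neurons, rose (0.27 [0.12 to 0.41]), and Hoxc11 stood at -0.13 [-0.41 to 0.15], so the genes go both ways. No other biological explanation was tested.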

How the results depend on the processing

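The smooth on GC content and length, TPM without spike-ins and protein-coding genes alone were chosen only after the result was seen. Genes detected, the count of shifted lists, the count of list levels and the count of pairs stayed within 1.5 times under every alternative run. On TPM the protein-coding share was 76.6%. The Pearson r was 0.963 with a pseudocount of 0.1, 0.995 without a filter and 0.996 on TMM-scaled CPM, and the Spearman rho 0.948 without a filter and 0.997 on CPM. The biological coefficient of variation was 0.0685 among genes with 100 counts in both libraries. Genes differing between pools numbered 75 with at least 100 counts, 4975 without a minimum ratio, and 164 and 49 in the edgeR exact test with an assumed variation of 0.1 and 0.2. The median leading transcript share was 94.8% on posterior means, and the share of 5′ HoxA and HoxD genes 82.5% on counts without length correction. Those counts reversed Fgf10 over Fgf8 (0.48), Bmp7 over Bmp4 (0.44) and Cyp26b1 over Aldh1a2 (0.63), since the alternative leaves out gene length. For the other changes the cause was not tested, except that a higher count minimum tests fewer genes.

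With each replicate left out, genes detected ranged from 14085 to 14096, the protein-coding share from 87.4% to 89.8%, list levels from 7 to 7, pairs from 36 to 37, the leading transcript share from 96.7% to 97.6% and the Hox share from 80.7% to 81.5%. Correlation, spread and between-pool results need both libraries. Of 89 values for genes named between pools 11 lost their call, of 113 list shifts 4 lost and 4 gained one, and of 205 pair values 3 reversed, 2 lost and 1 gained. Of 150 list levels 69 moved, of 87 transcript shares 6 and of 39 class shares 13. Of the 518 genes that differed 443 had fewer than 100 counts, and no alternative varied the depth. No paired analysis was possible because there is only 1 group.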

Other observations

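The test of spike-in spread was chosen before its result was seen. The gene families, the genes outside the fixed lists and the choice of which values to set side by side came after their values were seen.

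Guidance, adhesion and growth factor families were also expressed. All 8 ephrins and 11 of 14 Eph receptors reached 1 TPM in both libraries, with Ephb4 (56.7 ± 0.361 TPM), Epha7 (43.6 ± 3.37) and Epha4 (35.6 ± 4.03) the highest receptors. The Sox genes Sox11 (270.3 ± 8.86) and Sox4 (86.9 ± 5.58) exceeded the cartilage regulator Sox9 in the first case only. All 6 glypicans were detected, led by Gpc3 (1054 ± 68.7), and of the cadherins Cdh11 stood at 150.5 ± 0.714. The Igf system included Igfbp4 (637 ± 17.0) and Igfbp2 (212 ± 24.7), and the Notch pathway Notch2 (25.4 ± 0.156), Hes6 (76.9 ± 4.01), Hes1 (54.6 ± 2.01) and Hey1 (43.7 ± 2.52).

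Some values differed between the libraries beyond counting error. The mitochondrial gene mt-Nd4l had 83.48 and 256.64 counts, a log2 ratio of 1.93 (1.58 to 2.32). These counts are not whole, so some reads were shared with other entries and the split is uncertain. The gene IDs ENSMUSG00000090234 and ENSMUSG00000090407, of 1247 and 1251 nt, had 785 and 0.37 counts against 0 and 791 counts, and their sums were 785 and 791, a log2 ratio of 0.33 after scaling for depth. Another ID without a symbol, ENSMUSG00000103057, had 131 and 449 counts (2.09). Among Y-linked genes Ddx3y, Kdm5d and Uty had log2 ratios of -0.20, -0.23 and -0.31, against 0.13 [-0.01 to 0.26] for Eif2s3y, while Xist had 0.31 [0.27 to 0.36].

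The spread between the pools exceeded counting noise, and noise of library making and sequencing alone is a candidate explanation. The median absolute deviation of spike-in log2 ratios was 0.55 times that of genes with like counts (0.40 to 0.75; 65 spike-ins), and 0.30 times over the 18 spike-ins with 10000 counts or more. An interval below 1 had been set beforehand to count against this explanation. That reading was set aside only after the result was seen, because each pool gave 1 library and the step at which spike-ins were added is not given in the sources used here, so noise of library making and differences between pools cannot be told apart.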
